A study of Danio rerio with 2 samples.

How the data were processed

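The series compares gnl2 mutant and wild-type zebrafish embryos by direct hybridisation on 2 Agilent arrays with a red and a green channel. Per the labels, each extract came from 40 whole embryos at 22 hours post-fertilization, mutants came from crosses of heterozygous carriers, and wild types were of the TL strain. The labels do not state that the wild types were siblings of the mutants, and part of the collected embryos was used for genotyping. The labelled RNA was hybridised to a zebrafish expression array with 22575 spots. The series text describes biological replicates with a dye swap, and each array was therefore taken as 1 replicate. Both array titles end in the same number, which leaves open that the arrays share the same extracts, and p-values may then measure only technical spread. Array, replicate, dye orientation and any difference between slides cannot be told apart with 2 arrays.

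Per the file headers, the spot intensity values are mean pixel signals with median local backgrounds, read by Agilent Feature Extraction A.7.5.1. Its processed intensity values had spatial detrending on and local background correction off, and were dye-normalized with LOWESS smoothing of 0.25, per the file headers. The log10 ratio column is log10 of red (Cy5) over green (Cy3) processed signal, per the file headers, and the p-value column is the software's own error model for 1 array, per the file headers. The deposited value table holds log10 red over green with its sign not turned for the dye swap. It differed from the scanner files' log10 ratio by at most 0.00498 on array 1 and 0.00499 on array 2, and its medians were 0 and 0. Each array held 22575 spots, of which 1080 were controls and 21495 gene probes. On array 1, 185 red and 34 green spots were saturated and 665 gene probes carried outlier flags, and on array 2 the numbers were 100, 22 and 93.

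Signals were corrected with normexp (offset 50) on all spots, and normalized within each array by loess (span 0.3) with control and outlier spots at weight 0, in limma 3.58.1 under R 4.3.3. Outlier flags on either array removed 749 probes. A probe was kept if it was well above background in the mutant channel of both arrays or in the wild-type channel of both, which removed 1462. The ratio of array 2 was turned so that both arrays give mutant over wild type. A dye effect of equal size on both arrays cancels in the mean and stays in the residual. The SD across probes was 0.162 for the mutant over wild-type mean and 0.188 for red over green. Saturated spots were kept. A gene saturated in 1 genotype on both arrays has at most a bound, and none if the other genotype was saturated on 1 of them. A gene saturated in both genotypes on both arrays has none, and no fold is given for either kind.

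Gene names followed the reference tables of assembly GRCz12tu, used for names and for the order of neighbouring genes. Of the 21495 gene probes, 7323 were named by accession, 615 by symbol and 2360 by synonym, and 11197 kept the name in the file. Different probes of a gene were tested separately, and list tests took the probe with the highest mean intensity. Among the genes named, probes of a gene lay more than 0.5 apart in log2 ratio for ctsba, sesn3, fsta, ccnb1, fosab, fga, crygn1, rpl12, pdia4, rpl5b and ctslb, whose values are given.

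Probes were tested with limma's lmFit and eBayes on the mean log2 ratio, 2-sided, with Benjamini-Hochberg adjustment over 19284 probes and a threshold of 0.05. Each probe had 1 residual degree of freedom and 3.49 in total after pooling of the spread. A separate rule of size counted probes at least 2-fold in 1 direction on both arrays. The 20 gene lists and cell type marker lists were tested with limma's camera at a preset correlation of 0.01, 2-sided, with adjustment over the 20 lists. At the preset correlation the p-value rests on the spread between genes, not between arrays, and so does not measure variation between embryo pools. Statements that a list rose, fell or was called therefore describe these 2 arrays. With an estimated correlation, camera falls back on the 1 residual degree of freedom by construction. The estimate was 0.534 for the ribosomal protein list, 0.42 for erythroid, 0.182 for skeletal muscle, 0.164 for yolk and 0.153 for endothelium and heart. For these lists the p-values at the preset correlation may be too small. Among the other called lists described it lay between -0.0286 and 0.0196. At 0.0196 for ribosome biogenesis and 0.0135 for neural progenitors it was above the preset 0.01, so these p-values may be too small as well. Each estimate rests on 1 residual per gene, so a low one does not show that genes vary independently between embryo pools. Median ratios of lists were set beside 10000 random lists matched on intensity. Proportions were compared with Fisher's exact test, 2-sided.

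The named genes are, per direction, up to 12 with an adjusted p under 0.05, filled with genes of at least 2-fold on both arrays in order of the smaller ratio. They also include gnl2 and 10 other fixed genes whatever their values, and up to 4 members of each list with the largest mean ratio. For several lists only part of these members are described. The sample groups, the tests, the lists and this rule were fixed before the data were examined. The genes baxa, gadd45aa, rpl36 and the transcript ENSDART00000004535 fall outside the rule and were named after their values were seen. Of the fixed items, 1 gene and 1 list are not reported here, though counts over all lists include that list.

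Alternatives covered the background correction, Agilent's processed signals, the deposited value table, the normalization within and between arrays, the filter on dim probes, the eBayes prior, Agilent's error model, the size rule at 1.5-fold, single arrays, and for lists the correlation, ranks and the mean over probes. Leaving out probes saturated on either array was chosen after seeing the data. The steps were tested on simulated data with 19284 probes at the measured spread. Of 100 probes changed 4-fold 87 were called, of 100 changed 2-fold 3 were called, and 5 unchanged probes were called. The size rule found 98 and 39 of them, and 23 unchanged probes as well. All 10 simulated lists of 40 genes shifted by 0.2 on the log2 scale were called, and 0 of 10 unshifted ones. The simulated noise was drawn independently for each probe and array and held no dye effect. The simulation therefore does not test list calls where genes vary together or follow the dye. It also held 200 changed probes, and the adjusted p of a probe depends on how many others change. The share of 4-fold changes called there is therefore not the power in these data. In the data mdm2, at 4.85-fold, had an adjusted p of 0.4975 in limma, so the lack of calls does not speak against changes of that size.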

Results

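Whole zebrafish embryos homozygous for the bw41c allele of gnl2 were compared with wild-type embryos of the TL strain at 22 hours post-fertilization, to learn which transcripts differ in the mutants. Gnl2 is a nucleolar GTPase with a role in making the large ribosomal subunit. Total RNA from pools of 40 embryos was labelled with Cy3 or Cy5, and mutant and wild-type RNA were hybridised together on 2 arrays with the dyes swapped. Mutant RNA carried Cy5 on array 1 and Cy3 on array 2, and all ratios are given as mutant over wild type. Median red and green signals were 482 and 243 on array 1, and 305 and 204 on array 2. Red and green signals were well above background at 96.4% and 94.0% of gene probes on array 1, and at 94.5% and 92.7% on array 2. After filtering, 19284 probes for 16295 genes or transcripts were tested, with n = 2 arrays for every value. The number of arrays limits the precision.

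The RNA of gnl2 itself was measured by a single probe. Its log2 ratio was -0.99 on array 1 and -2.27 on array 2, with a mean of -1.63 ± 0.91 (SD, n = 2), or 0.323 of the wild-type level. The adjusted p in limma was 1.00. With median centring in place of loess the mean was -1.58 with an adjusted p of 1.16e-05, while under every other tested alternative the adjusted p was 1.00. The position of the probe relative to the bw41c lesion is not given in the sources used here, so the value does not check the genotype labels.

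Transcripts at least 2-fold different in the same direction on both arrays were almost all higher in the mutants. These numbered 24 probes for 23 genes or transcripts, against 1 probe that was at least 2-fold lower, while 14 further probes were at least 2-fold in opposite directions. With Agilent's processed signals the numbers were 30 higher and 6 lower. In the simulated data at the measured spread the same rule also found 23 unchanged probes, so single probes that pass it may be noise. The log2 ratio of mdm2, which encodes a ubiquitin ligase, was 2.28 ± 0.07, a ratio of 4.85-fold. The initiator caspase gene casp8 had a log2 ratio of 2.46 ± 0.22 (5.51-fold), and ccng1, encoding cyclin G1, one of 2.32 ± 0.85, with its mutant signal saturated on 1 array. The stress-response gene sesn3 had a log2 ratio of 2.46 ± 0.79, whereas a dimmer sesn3 probe gave 0.09. The forkhead factor gene foxo3b had 1.66 ± 0.16. The pro-apoptotic Bcl-2 family gene baxa had 1.56 ± 0.68, and the DNA damage response gene gadd45aa 1.33 ± 0.42.

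The growth factor gene igf2a had a log2 ratio of 1.68 ± 0.03, the kinase gene vrk2 1.76 ± 0.18, and upb1, which encodes an enzyme of pyrimidine breakdown, 1.55 ± 0.03. The gelatinase gene mmp2 had 1.52 ± 0.04 and gtpbp1l 1.40 ± 0.05. The largest mean belonged to 1 of the 2 probes for ctsba, a cathepsin B gene, at 3.82 ± 2.02, or 38.0-fold and 5.26-fold on the arrays. The other ctsba probe gave -0.49. The probe at least 2-fold lower on both arrays is annotated to the transcript ENSDART00000004535, at -1.27 ± 0.03.

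Cell cycle inhibitors and neurogenic genes fixed beforehand had small ratios. The log2 values were 0.23 ± 0.18 for cdkn1bb, -0.05 ± 0.14 for cdkn1ca, -0.005 ± 0.09 for the retinal proneural gene atoh7 and -0.02 ± 0.02 for neurod1. All probes of cdkn1bb lay between -0.05 and 0.23. Its paralog cdkn1ba, which was not among the fixed genes, had a larger ratio that is given further below. The cyclin D1 gene ccnd1 had 0.29 ± 0.43. The related nucleolar GTPase genes gnl3 and gnl3l had 0.18 ± 0.33 and 0.11 ± 0.20. The directions of atoh7 and neurod1 turned under other normalizations, to 0.002 for atoh7 with Agilent's processed signals and 0.02 for neurod1 with median centring. No probe on the array carries the name cdkn1a.

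In limma, 0 of the 19284 probes reached an adjusted p under 0.05, and the smallest adjusted p was 0.498. At an unadjusted p under 0.05 there were 632 probes, 392 higher and 240 lower in the mutants, where 964 would be expected by chance. Median centring in place of loess gave 38 probes at an adjusted p under 0.05, 34 of them higher. Agilent's error model of single arrays, at a p under 0.01 on both arrays, gave 98 probes higher and 35 lower, besides 289 with opposite directions. The turned ratios of the arrays correlated negatively across probes, which are not independent replicates (Pearson r = -0.149, Spearman rho = -0.197), and rpl36 was among the probes at least 2-fold in opposite directions, at -3.43 and 3.49.

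**Figure D1:**
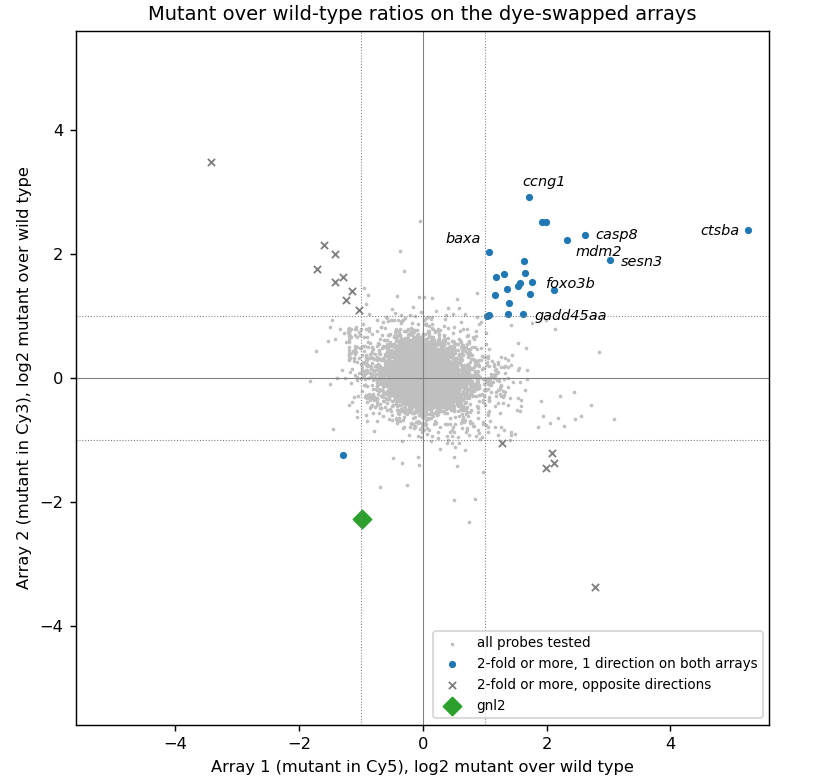
Log2 mutant over wild-type ratios of all probes tested on array 1 (horizontal axis, mutant in Cy5) against array 2 (vertical axis, mutant in Cy3), with dotted lines at 2-fold. Of the probes at least 2-fold in 1 direction on both arrays, 24 lie at the upper right and 1 at the lower left.

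**Figure D2:**
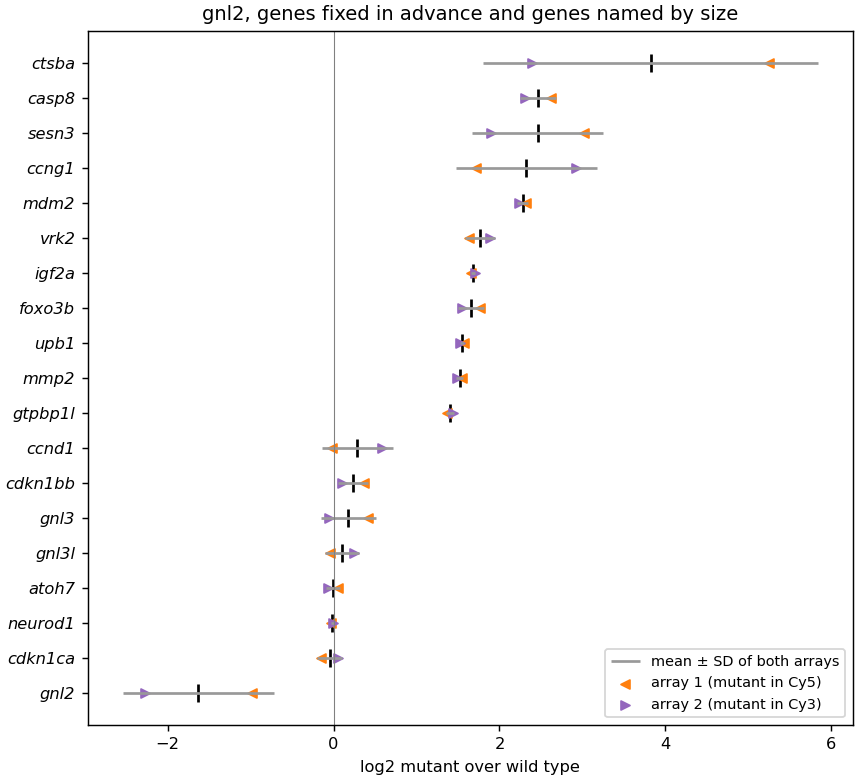
Log2 mutant over wild-type ratios of gnl2, of the genes fixed beforehand and of those named for their size, with triangles for the arrays, ticks for the mean and lines for the mean ± SD (n = 2). The mean for gnl2 is -1.63 and that for mdm2 2.28, with an SD of 0.91 and 0.07.

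The list of apoptosis machinery, which holds caspases and Bcl-2 family members but not casp8 and baxa, was not called. Its 17 measured genes had a median of 0.000483 and a mean of -0.02, with a test pointing down (camera adjusted p = 0.477). In limma 0 members had an unadjusted p under 0.05, and 0 were called when adjusted over the list alone or over all genes tested. The largest ratios among its members were those of mcl1b at -0.23 ± 0.36, birc5a at -0.18 ± 0.18, bcl2l10 at 0.18 ± 0.30 and dffb at -0.15 ± 0.08.

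Ribosome biogenesis factors rose slightly in the mutant RNA of these arrays. Their median log2 ratio was 0.15 over 78 genes (camera adjusted p = 1.99e-08, or an adjusted p of 0.47 with an estimated correlation). The ratio was higher on both arrays for 33 of them, lower on both for 6 and split for 39. The assembly factor gene rrs1 had 0.54 ± 0.06, and its other probe 0.92. The RNA polymerase I and III subunit gene polr1c had 0.69 ± 0.60 and noc3l 0.61 ± 1.32, with opposite directions on the arrays. The small-subunit processome gene utp11, which lies 3 genes from gnl2, had -0.52 ± 0.02. The medians on the arrays were 0.08 and 0.20.

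Cytosolic ribosomal proteins fell in the mean of the arrays, with a median log2 ratio of -0.20 over 68 genes (camera adjusted p = 1.47e-08, or an adjusted p of 0.61 with an estimated correlation). The arrays did not share this direction, with medians of -0.79 on array 1 and 0.24 on array 2. Only 17 genes were lower on both arrays, 1 was higher and 50 were split. The gene rpl10a was lower on both, at -0.59 ± 0.12. The ratios of rpl12 (-0.62 ± 0.77) and rpl5b (-0.52 ± 0.59) rest on saturated probes, in the mutant channel of array 1 for both genes and also in the wild-type channel of array 2 for rpl12. All probes of these genes lay between -0.66 and 0.03 for rpl12 and between -0.52 and 0.06 for rpl5b. For 7 genes, rps15 among them, 1 genotype was saturated on both arrays and the other on 1 array, so that the mean ratio has no bound. For 11 more, both genotypes were saturated on both arrays, which also leaves no bound, and the median over these spots was -0.20 like that of the list. In all, 49 of the 68 genes rested on a probe saturated on at least 1 array, so most of the mean ratios include a saturated signal. Along red over green the list median was -0.46 (adjusted p = 6.98e-21 by camera), and without saturated probes the mutant over wild-type median was -0.04 over 41 genes. For most of these 41 genes another probe stood in for a saturated one.

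Genes of DNA replication and S phase fell in the mutant RNA of these arrays. Their median was -0.13 over 39 genes (camera adjusted p = 1.79e-09, or an adjusted p of 0.47 with an estimated correlation). Of these genes 21 were lower on both arrays and 2 higher, and the medians on the arrays were -0.12 and -0.17. The ribonucleotide reductase gene rrm2l had -1.14 ± 0.44, the dihydrofolate reductase gene dhfr -0.42 ± 0.04, dut -0.41 ± 0.57 and the DNA polymerase epsilon subunit gene pole2 -0.36 ± 0.14. The G2 and mitosis list fell as well, with a median of -0.11 over 36 genes (camera adjusted p = 1.61e-07, or an adjusted p of 0.47 with an estimated correlation). Its medians on the arrays were -0.12 and -0.08, and 20 genes were lower on both and 4 higher. The spindle checkpoint kinase gene ttk had -0.41 ± 0.21, dlgap5 -0.35 ± 0.06 and the replication licensing inhibitor gene gmnn -0.41 ± 0.61. The cyclin B1 gene ccnb1 had -0.43 ± 0.01 at its brightest probe and 0.76 at another.

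Markers of neural progenitors and the eye field fell, with a median of -0.09 over 65 genes (camera adjusted p = 2.71e-10, or an adjusted p of 0.47 with an estimated correlation). On both arrays 38 genes were lower and 5 higher, and the medians on the arrays were -0.16 and -0.07. The brain fatty acid binding protein gene fabp7a had -0.82 ± 0.04, and its 3 probes lay between -0.82 and -0.75. The progenitor factor gene sox2 had -0.61 ± 0.35 and the retinal homeobox gene rx2 -0.59 ± 0.46, whereas notch3 had 0.71 ± 1.43 with opposite directions on the arrays. The list was also called lower along red over green, at a median of -0.04 (camera adjusted p = 0.0481). Proneural and neuronal genes were called lower with a median of -0.01 over 68 genes, inside the range of -0.02 to 0.03 of random lists (camera adjusted p = 0.0138, or an adjusted p of 0.47 with an estimated correlation). Of these genes 21 were lower on both arrays, 11 higher and 36 split. That call ended on ranks (adjusted p = 0.0545) and with median centring (adjusted p = 0.394), out of a range from 0.00663 to 0.47 over the alternatives. The bHLH genes neurod4 and ascl1b had -0.51 ± 0.20 and -0.39 ± 0.06, ebf2 had -0.28 ± 0.05 and isl2b 0.27 ± 0.22.

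Several lists of differentiated tissues were called higher in the mean of the arrays, but their medians on array 2 were near 0. Skeletal muscle genes had a median of 0.11 over 54 genes (adjusted p = 2.55e-05, or an adjusted p of 0.61 with an estimated correlation), with actc1b at 0.45 ± 0.01 and 0.11 at its other probe, and desma at 0.53 ± 0.45. The largest mean in this list was that of tnnt1 at 1.25 ± 1.8, with opposite directions on the arrays, and acta1b had 0.47 ± 0.38. Of the 54 genes 18 were higher on both arrays, 4 were lower and 32 were split. Erythroid genes had a median of 0.09 over 24 genes (adjusted p = 5.52e-04, or an adjusted p of 0.61 with an estimated correlation), with the embryonic globin gene hbbe2 at 0.60 ± 0.02. Endothelium and heart genes had 0.07 over 28 genes (adjusted p = 8.05e-04, or an adjusted p of 0.61 with an estimated correlation), with clec14a at 0.35 ± 0.04. Yolk syncytial layer, endoderm and liver genes had 0.05 over 42 genes (adjusted p = 0.0125, or an adjusted p of 0.61 with an estimated correlation), with the fibrinogen gene fga at 0.83 ± 0.99 and 0.04 at its other probe. The medians on array 1 were 0.18, 0.25, 0.17 and 0.09 in this order, against -0.03, 0.006, -0.007 and -0.03 on array 2. The arrays thus did not share a direction for muscle, endothelium and heart, and yolk, and each median on array 2 lay inside its random range. The muscle and erythroid lists were also called along red over green (adjusted p = 0.0126 for each).

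Hatching gland genes rose with a median of 0.24 over 9 genes, 7 of them higher on both arrays (camera adjusted p = 0.00286, or an adjusted p of 0.47 with an estimated correlation). The medians on the arrays were 0.25 and 0.09, the latter inside its random range of -0.14 to 0.19. With the mean over all probes of a gene the list stayed called (camera adjusted p = 0.0147), but its median was 0.09. That lies inside the random range of -0.096 to 0.132, which was drawn with 1 probe per gene. The hatching enzyme gene he1.2 had 0.69 ± 0.52, while the protease gene ctslb had -0.58 ± 0.39 with its mutant signal saturated on 1 array, and its 3 probes lay between -0.58 and -0.01. Notochord and floor plate genes rose with a median of 0.09 over 26 genes (camera adjusted p = 0.00229, or an adjusted p of 0.47 with an estimated correlation), with the collagen-modifying enzyme gene plod3 at 0.25 ± 0.03. The list medians on the arrays were 0.05 and 0.05, each inside its random range. On both arrays 7 genes were higher and 1 was lower, and 18 were split. Larger means than that of plod3 were those of ntd5 (0.31 ± 0.70) and col9a2 (0.26 ± 0.39), both split between the arrays, and lamb1a (0.26 ± 0.22). Genes of the heat shock, unfolded protein and integrated stress responses rose with a median of 0.07 over 41 genes (camera adjusted p = 0.0309, or an adjusted p of 0.499 with an estimated correlation). The medians on the arrays were 0.05 and 0.08, the former inside its random range. The immediate early gene fosab had 1.32 ± 0.62 and 0.21 at its other probe, and the translation repressor gene eif4ebp1 had 0.58 ± 0.12. The disulfide isomerase gene pdia4 had -0.63 ± 0.28 and 0.01 at its other probe. This call ended on ranks (adjusted p = 0.0695) and without the normexp offset (adjusted p = 0.059), out of a range from 0.00443 to 0.499 over the alternatives.

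The lists for segmentation and tailbud, myeloid cells, epidermis, lens, and neural crest and pigment were not called, at camera adjusted p of 0.477, 0.498, 0.39, 0.8 and 0.477. Their medians were 0.02, 0.01, 0.01, -0.03 and -0.01. In the epidermis list the mean was -0.05 and the test pointed down against a median above 0, and in the lens list the mean was 0.04 against a median below 0 and a test pointing down. The retinoic acid hydroxylase gene cyp26a1 had 0.55 ± 0.24, the leukocyte gene lcp1 0.55 ± 0.36, icn of the epidermis -0.52 ± 0.03, crygn1 of the lens 0.78 ± 0.33 (0.006 at its other probe) and sox9a of the neural crest -0.33 ± 0.11. Of the 20 lists, 14 were called, 9 higher and 5 lower, and 0 were called with an estimated correlation. In each list described here, 0 members were called by limma when adjusted over the list alone, and 0 over all genes tested. At an unadjusted p under 0.05 there were 0 higher and 11 lower in the neural progenitor list, 6 and 1 in each of the ribosome biogenesis and skeletal muscle lists, 0 and 5 in each of the DNA replication, mitosis and proneural lists, and 4 and 2 in the heat shock list. The numbers were 3 and 0 in each of the erythroid and endothelium lists, 0 and 3 in the ribosomal protein and epidermis lists, and 2 and 1 in the hatching gland and yolk lists. They were 1 and 0 in the notochord, segmentation, myeloid and lens lists, 0 and 1 in the neural crest list, and 0 and 0 in the apoptosis list.

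**Figure D3:**
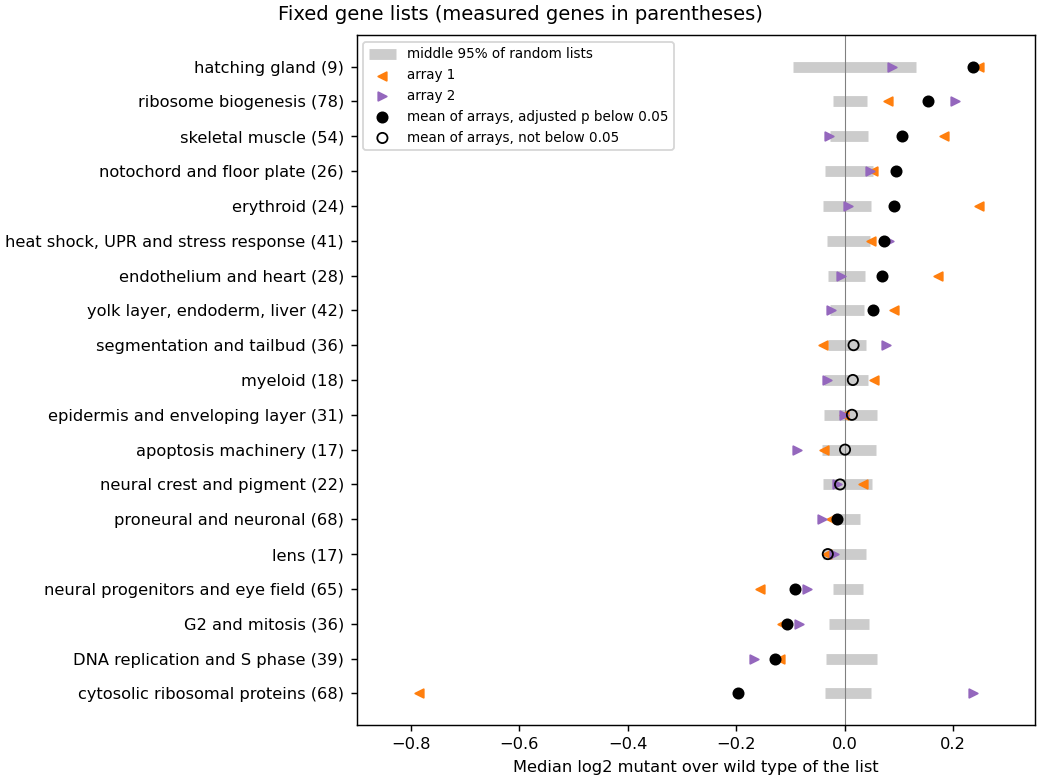
Median log2 mutant over wild-type ratio of the fixed lists described, with circles for the mean of the arrays, triangles for each array and grey bars for the middle 95% of 10000 random lists of like intensity. The bars belong to the mean of the arrays, and the wider random ranges of the single arrays are not drawn. The ribosome biogenesis factors lie at 0.15, and the ribosomal proteins at -0.79 on array 1 and 0.24 on array 2.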

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

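The choice of alternatives was made before the data were examined, except that leaving out saturated probes was chosen only after the results with them were seen. The count of 0 probes at an adjusted p under 0.05 in limma held under 9 alternatives, of which Aquantile moves no ratio, and the added one, with 501 to 680 probes at an unadjusted p under 0.05. It became 38 with median centring in place of loess, where eBayes gave all probes nearly 1 shared variance and so called by size, and gnl2 was then called at -1.58. It became 133 with Agilent's error model of single arrays, which leaves out the spread between arrays. Leaving out an array could not be tested for this count, since no residual degree of freedom is left.

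The 25 probes of the size rule became 59 at 1.5-fold, a looser rule by construction, and 258 without replicate 2 and 85 without replicate 1. Other settings gave 21 to 36. Of the 20 lists, 11 to 14 were called, but 0 with an estimated correlation, which rests on 1 degree of freedom. Between single arrays the median went from -0.79 without replicate 2 to 0.24 without replicate 1 for cytosolic ribosomal proteins. In the same order it went from 0.18 to -0.028 for skeletal muscle, 0.091 to -0.025 for yolk syncytial layer, endoderm and liver, and 0.17 to -0.0073 for endothelium and heart. Uncalled results near 0 also turned, and the cause was not tested. The test of the lens list pointed up at a median of -0.022 with no filter on dim probes and -0.031 with probes well above background in both channels. With median centring, neural crest and pigment had 0.012 and neurod1 0.022, and atoh7 had 0.0024 with Agilent's processed signals and 0.0025 with the deposited value table. As dim, 1462 probes were removed, which does not show how far low signal affects the probes kept. Without the normexp offset the size rule gave 28 probes higher and 3 lower, against 24 and 1 with it.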

Other observations

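All tests in this part were chosen only after the result was seen, and for the removal of saturated probes from the ribosomal protein list this was the list result with them, since the value without them was not yet known.

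Further genes were at least 2-fold higher in the mutants on both arrays, and were named after their values were seen. The poly(ADP-ribose) polymerase gene parp3 was 2.47-fold higher in the mean of the arrays, rasl11b 2.30-fold and tspan18a 2.03-fold. The follistatin gene fsta had a log2 ratio of 1.41 ± 0.31 at 1 probe and 0.34 and 0.05 at others. The Wnt agonist gene rspo1 had 1.25 ± 0.12. The cell cycle inhibitor gene cdkn1ba, which did not reach 2-fold and was also named after its value was seen, had 0.59 ± 0.09, beside 0.23 for its paralog cdkn1bb.

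The list calls were weighed against dye and saturation. A dye effect behind all 14 calls would leave no list outside the random range in its called direction on both arrays. On that measure 5 lists lay outside, among them ribosome biogenesis, DNA replication, mitosis and neural progenitors. Neural progenitors were also called along red over green. The count speaks only against a dye effect behind every call, and leaves it open for the other called lists. Random lists hold unrelated genes, so lists whose genes vary together may leave the range more easily. For the ribosomal protein list a dye effect of unequal size on the arrays may lie behind the call. Its median was -0.464 along red over green against -0.20 for mutant over wild type. That -0.464 covers all 68 genes, 49 of them on a probe saturated on at least 1 array. Genes saturated in both genotypes on both arrays, such as rps2 and rpl23a, gave nearly identical ratios, -1.19 on array 1 and 0.80 on array 2. Without saturated probes the medians on the arrays were -0.11 and 0.02, so much of the -0.464 rests on saturated spots. The mutant over wild-type median was then -0.0379 (camera adjusted p = 0.00521), and a dye effect and saturation cannot be told apart for the call.

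Beside gnl2, the genes rspo1 at 1.25, utp11 at -0.52 and pou3f1 at -0.29 had an unadjusted p under 0.05, all on the same side of gnl2, while the other side had no tested probe within 7 genes. They make up 3 of 3 probes (100%) of the 5 nearest genes on either side against 4.47% of others, and 3 of 14 probes within 10 genes. The windows were set around values already seen, so these shares do not test a local effect, and such an effect from the mutation or a short strain stretch stays open. A stretch over 100 genes on either side stays open as well, at 5.48% of 73 probes (exact 95% interval 1.51 to 13.4) against 4.49% of others (Fisher's exact p = 0.571).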
